A study of Mus musculus with 2 samples.

How the data were processed

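Gene expression was measured in LSK cells, the bone marrow cells that lack lineage markers and carry Sca-1 and c-Kit and that hold the haematopoietic stem cells and multipotent progenitors. Per the labels' protocols, the cells came from C57BL/6 mice and were sorted by flow cytometry, total RNA was isolated with Trizol, and the RNA was amplified and labelled with Cy3 by the Quick Amp kit of Agilent. The labels give 1 array of wild-type cells and 1 array of PAD4-deficient cells. Whether RNA was pooled from several mice, and the sex of the mice, is not given in the sources used here. Both arrays lay on the same slide and in the same scan. The days of sorting, RNA isolation and labelling are not given in the sources used here.

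Per the file headers, both arrays were 1-colour arrays of Agilent design 014868, read with Feature Extraction 9.5.3.1, and probe coordinates refer to the mouse build mm8. The submitters' processing notes name Agilent Feature Extraction 9.5. The deposited scanner files give the spot intensity on a linear scale, as a processed signal after the authors' background subtraction and spatial detrending, with an error estimate per spot, beside the mean and local background signals. The deposited value table is on a log2 scale. It was checked against the scanner values: each column was the log2 of the median processed signal of a probe's spots minus a constant, 9.67 for the wild-type array and 9.62 for the PAD4-deficient array, for all 41174 probes. The column medians were -3.59 and -3.53. Genes were not centred in that table, and its direction was that of the scanner values, so scale, centring and direction were all settled.

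The main value was log2 of the processed signal, averaged over the unflagged spots of a probe, minus the 75th percentile of all non-control probes of that array. Control spots and spots flagged as outliers were left out, which removed 4 probes with no unflagged spot on an array. A probe was measured when it was well above background on both arrays. The value of a gene came from its brightest measured probe, and differences between probes of a gene are given where they matter. The difference was PAD4-deficient minus wild-type. Its error was the spot error of Feature Extraction, propagated over both arrays, and covers the measurement of a spot and not the variation between mice. Probes were named with the RefSeq table of GRCm38.p6, used for names and neighbours only: 24367 probes matched through an accession, 6307 through the symbol, 2425 through a synonym, and 8075 kept the name in the files. A gene well above background on 1 array only was given as an at-least fold: the bright value against the higher of the dim probe's own value and the lowest value among probes well above background on the dim array.

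With 1 array per group no test across groups was possible, and no difference between the genotypes had a replicate check. Genes were counted at a 2-fold difference. Each of 30 gene lists, fixed before the data were examined, was described by its median difference and by the percentile of that median among 10000 random lists of the same size, matched on mean expression in 20 bins. Such a percentile describes these arrays only. The named genes followed a rule fixed at the same time: the Padi genes, Myc, Lef1, Hdac1, Kit and Ly6a; the 10 genes with the largest difference in each direction with a reference symbol and all measured probes at least 1.5-fold different in the same direction; the largest at-least folds; and up to 2 list members per direction with a difference of at least 1.5-fold. A list member that the rule takes is not reported here. Other list members are named as examples and were chosen after their values were seen. The alternatives were normexp background correction with an offset of 50, quantile normalization, median scaling, the 75th percentile of detected probes, loess on intensity with a window of 0.3, the deposited value table, the mean over probes, looser signal filters and other folds. A count restricted to genes with 2 or more measured probes, normexp without its offset for the Y-linked probes, and 3 further gene lists were chosen after seeing the data.

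The steps were tested on simulated data with known changes in 17021 genes: all of the 50 genes per direction simulated with a 3-fold change passed 2-fold (100%), and 6 of 16801 unchanged genes passed it under the scanner error alone. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and statsmodels 0.14.6 was used, with limma 3.58.1 in R 4.3.3 for normexp.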

Results

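LSK cells from wild-type and from PAD4-deficient mice were compared on 1 array each. PAD4, encoded by Padi4, converts arginine residues of histones and other proteins to citrulline. Of 41174 probes, 26310 (63.9%) were well above background on the wild-type array and 26399 (64.1%) on the PAD4-deficient array. The 75th percentile of the processed signal was 814 and 787. Probes printed in several spots had a median SD between spots of 0.06 and 0.05 on the log2 scale. The probes measured on both arrays represented 17021 genes. The number of arrays limits the precision: with 1 array per group, no difference between the genotypes has a replicate check, and the errors given with differences are scanner errors only.

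Padi4, the targeted gene, was lower on the PAD4-deficient array by all 3 of its probes. Its brightest probe (mm8 chromosome 4, 140017954 to 140018013) had a processed signal of 12879 on the wild-type array and 2670 on the PAD4-deficient array, a log2 difference of -2.22 with an error of 0.20. The signal that remained was 21.5%, 21.2% and 24.2% of the wild-type signal for the 3 probes. Which part of the gene was deleted, and so whether these probes lie in it, is not given in the sources used here. The other Padi genes lie in the same cluster on chromosome 4. Padi1 differed by -0.10, Padi2 by -0.19 and Padi3 by -0.41, with errors of 0.21, 0.20 and 0.33. Padi6 was well above background on the PAD4-deficient array only, at least 8.25-fold higher by its single probe. The 4 measured Padi genes had a median of -0.30 (percentile 1.19). They include Padi4 itself and leave out Padi6, so this median does not show that the other Padi genes fell together. With normexp background correction this median was -0.14 and Padi3 differed by -0.10. The 19 measured genes that flank the cluster had a median of -0.05 (percentile 8.64; 0.019 with the mean over probes), and none of them differed by 1.5-fold.

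Myc, a transcription factor of growth and division, was higher on the PAD4-deficient array. Its brightest probe (mm8 chromosome 15, 61819627 to 61819687) had a signal of 5751 on the wild-type and 10137 on the PAD4-deficient array, a log2 difference of 0.87 with an error of 0.20. Another probe gave 0.99, and the dimmest gave 0.24, so the probes did not have the same size of difference. Lef1, a transcription factor of the Wnt pathway, was dim and had a log2 difference of 0.98 (error 0.23), with 1.20 at its second measured probe. Hdac1, a histone deacetylase, differed by 0.13, within its error of 0.20. Among 15 measured Wnt, TCF and LEF targets the median was 0.10 (percentile 86.8); Tcf7, at 0.96 with 0.54 at its second probe, and Lef1 were the members furthest above the wild-type array. The 40 MYC target and ribosome biogenesis genes had a median of 0.10 (percentile 99.8), with 29 above 0; Hspd1 had 0.33 and Rrp12 -0.65.

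**Figure D1:**
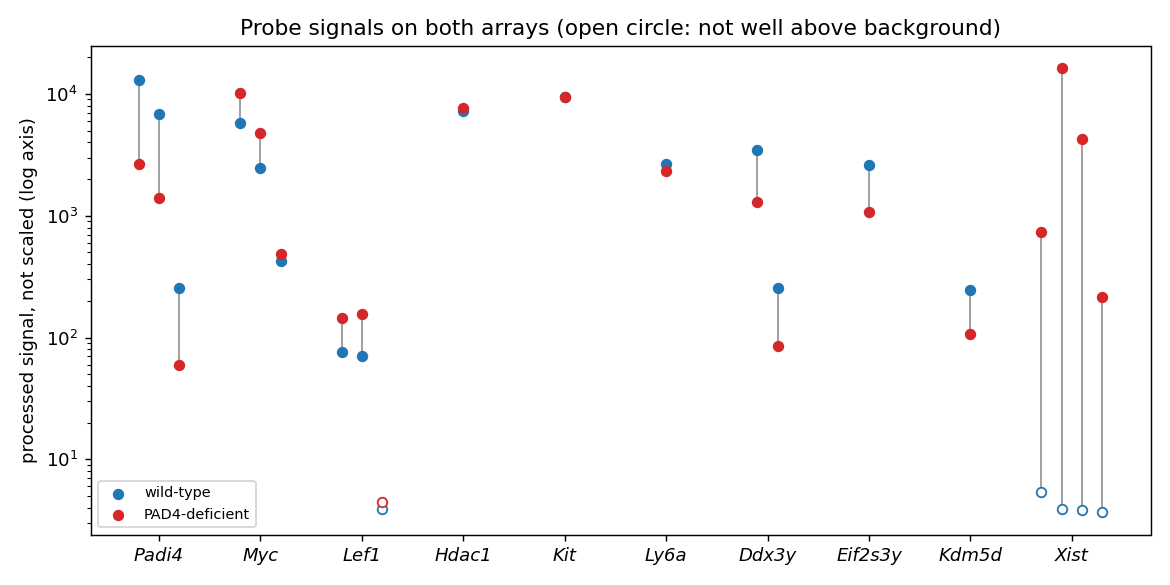
Processed signal (log axis, not scaled between arrays) of each probe of 10 genes on the wild-type (blue) and PAD4-deficient (red) arrays, 1 array per group, with a line joining the same probe and open circles for probes not well above background. All 3 Padi4 probes were lower and all 4 Xist probes higher on the PAD4-deficient array.

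Genes of committed blood lineages were higher on the PAD4-deficient array. Of 21 measured erythroid genes, 11 were at least 1.5-fold higher and none was 1.5-fold lower. The list median was 0.65, above all 10000 matched random lists (percentile 100). Ermap, a red cell membrane protein, differed by 2.52 (error 0.28), Rhd by 1.99 (error 0.22), Eraf, a globin chaperone, by 1.80, Car1 by 1.73 and Klf1, an erythroid transcription factor, by 1.63. Other transcripts abundant in erythroblasts were lower or near 0: Alas2 differed by -0.47, Slc4a1 by 0.05, Hba-a1 by -0.22 and Hba-a2 by -0.23. Hbb-bt differed by 0.42 at its brightest probe and by 0.03, 0.00 and -0.06 at the others. Of 14 mast cell and basophil genes, 7 were at least 1.5-fold higher and 1, Il4, at least 1.5-fold lower (-0.78), with a list median of 0.61 (percentile 100). Gzmb, a granzyme, differed by 1.98 and Hdc, which makes histamine, by 1.39.

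Of 23 neutrophil granule and granulocyte genes, 21 were above 0 and 5 at least 1.5-fold higher, with a median of 0.41 (percentile 100). Elane, neutrophil elastase, had a signal of 296 on the wild-type and 1086 on the PAD4-deficient array, a log2 difference of 1.92 (error 0.20), and Ms4a3 differed by 1.79. Of 22 monocyte, macrophage and dendritic cell genes, 8 were at least 1.5-fold higher, with a median of 0.41 (percentile 100). F13a1, coagulation factor XIII A, differed by 1.61, Ccr2, a chemokine receptor, by 1.48 and H2-Eb1, an MHC class II chain, by 1.39. Other members of this list were near 0, such as Csf1r (0.10), Lyz2 (0.06), Cd68 (0.07) and Ctss (-0.02). Of 15 B cell genes, 7 were at least 1.5-fold higher, with a median of 0.55 (percentile 100). Pax5, the B cell transcription factor, differed by 1.23, Pou2af1 by 1.21 and Vpreb3 by 1.18. Of 19 megakaryocyte and platelet genes, 4 were at least 1.5-fold higher, with a median of 0.21 (percentile 100): Selp, P-selectin, differed by 0.88 with 0.37 at its second probe, and Clu by 0.64. The medians of the monocyte and B cell lists were 0.25 and 0.24 with normexp background correction, over 1.5 times lower than the main values. These lists mark committed blood lineages, both progenitors and the mature cells that a lineage-negative gate is meant to remove. The same arrays also differed in the sex-linked transcripts Xist, Ddx3y and Eif2s3y.

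**Figure D2:**
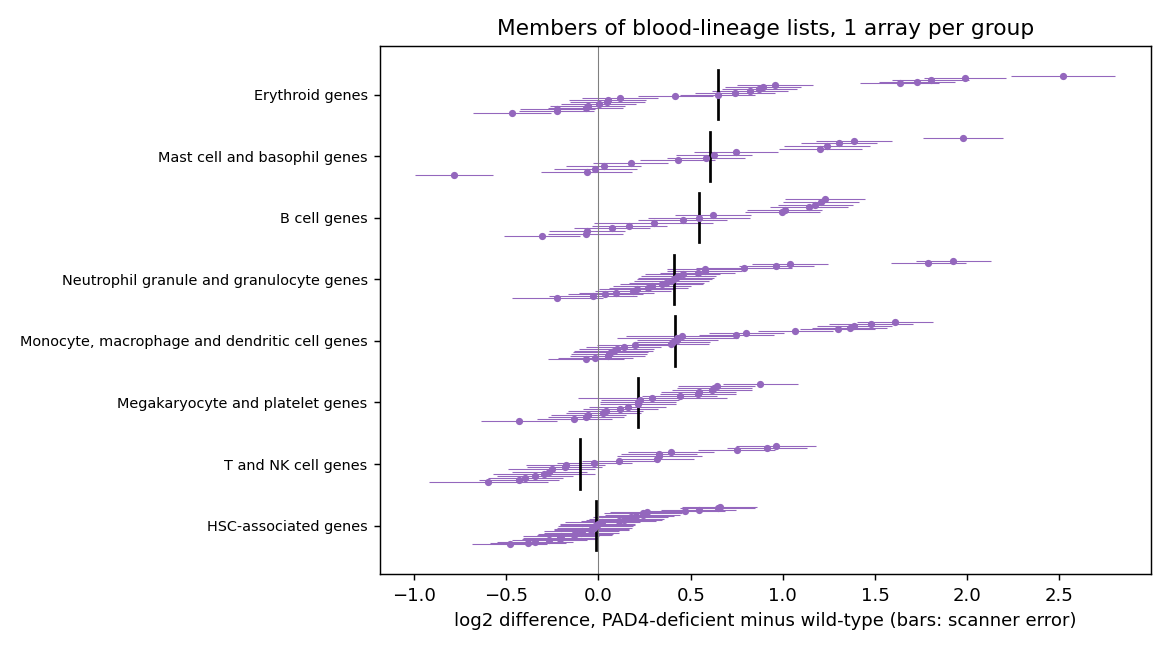
Log2 difference (PAD4-deficient minus wild-type, x axis) of each measured member of 8 gene lists, with scanner error bars and a black line at the list median, from 1 array per group. The medians of the erythroid, mast cell and B cell lists lay at 0.65, 0.61 and 0.55, and that of the stem cell list at -0.01.

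With the main signal filter, the medians of the stem cell list and of the T and NK cell list did not share this direction. The 30 HSC-associated genes had a median of -0.01 (percentile 25.9). Mycn (0.66, with 0.52 at its second probe) and Gfi1b (0.65) were at least 1.5-fold higher. Gfi1b is also a member of the erythroid list. The 19 multipotent and lymphoid-primed progenitor genes had a median of -0.05 (percentile 9.12). Flt3, the receptor of lymphoid-primed progenitors, was lower (-0.67, error 0.20), as was Ccr9 (-0.67), while Rag1, of the antigen receptor recombinase, was higher (1.14) and Il7r had 0.65 at its brightest probe with a second probe near 0. The 18 T and NK cell genes had a median of -0.10 (percentile 2.33), but 3 were at least 1.5-fold higher and 1 was 1.5-fold lower. Tcf7 had 0.96, Il2rb 0.91 and Prf1 -0.60. This median turned to 0.046 when genes above background on 1 array only were included, and to 0.19 with no filter on signal. Its direction thus depended on the filter. With normexp the list median was -0.039 and Prf1 had -0.11. The 11 stromal and endothelial genes had a median of -0.12 (percentile 4.24), with Cxcl12 at -1.51 and Bgn at -0.63; with normexp the median was -0.076 and Bgn had -0.41. Of the 10 measured sort markers (median 0.11, percentile 88.3), Kit differed by 0.07 and Ly6a, which encodes Sca-1, by -0.14, each within its error of 0.20.

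Differences in cell cycle and stress genes were small. The 34 G1/S and DNA replication genes had a median of 0.07 (percentile 91.1) and the 33 G2/M and mitosis genes 0.08 (percentile 96.3), with no member 1.5-fold different. The 17 CDK inhibitors and quiescence genes had a median of -0.01 (percentile 31.9) and the 25 p53 targets -0.01 (percentile 29.1), or 0.039 with normexp. Cdkn1a, the p21 inhibitor and a member of both lists, was lower, with signals of 6828 and 4308 and a difference of -0.61 (error 0.20). The 23 NF-kappaB and inflammatory genes had a median of -0.15 (percentile 0.05), with 20 below 0; Relb, an NF-kappaB subunit, had -0.65. The 30 immediate early and stress genes had a median of -0.10 (percentile 0.06), with Egr2 at -0.83 and Egr3 at -0.76 with -0.44 at its second probe. Among 11 Notch targets (median -0.03, percentile 25.4), Hes1 had -0.85 and Hey1 -0.68; the median was -0.16 with the mean over probes and 0.066 with no filter on signal. Among 33 type I interferon response genes (median 0.03, percentile 61.2), Irf7 had -0.90 and no other member was 1.5-fold different. Among 24 apoptosis genes (median 0.06, percentile 80.8), Bcl2a1b had 0.94 and Bmf -0.62 with -0.09 at its second probe.

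Of 20 measured histone genes, 17 were above 0, with a median of 0.19 (percentile 100); H3c1 had 0.84, and H1f3 0.75 at its brightest probe with 0.05 at the other. The 33 chromatin regulator genes had a median of 0.03 (percentile 63.9) and no member 1.5-fold different. The 28 oxidative phosphorylation genes had a median of 0.12 (percentile 99.8), the 33 ribosomal protein genes 0.08 (percentile 91.3) and the 23 glycolysis and hypoxia genes -0.03 (percentile 7.92).

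**Figure D3:**
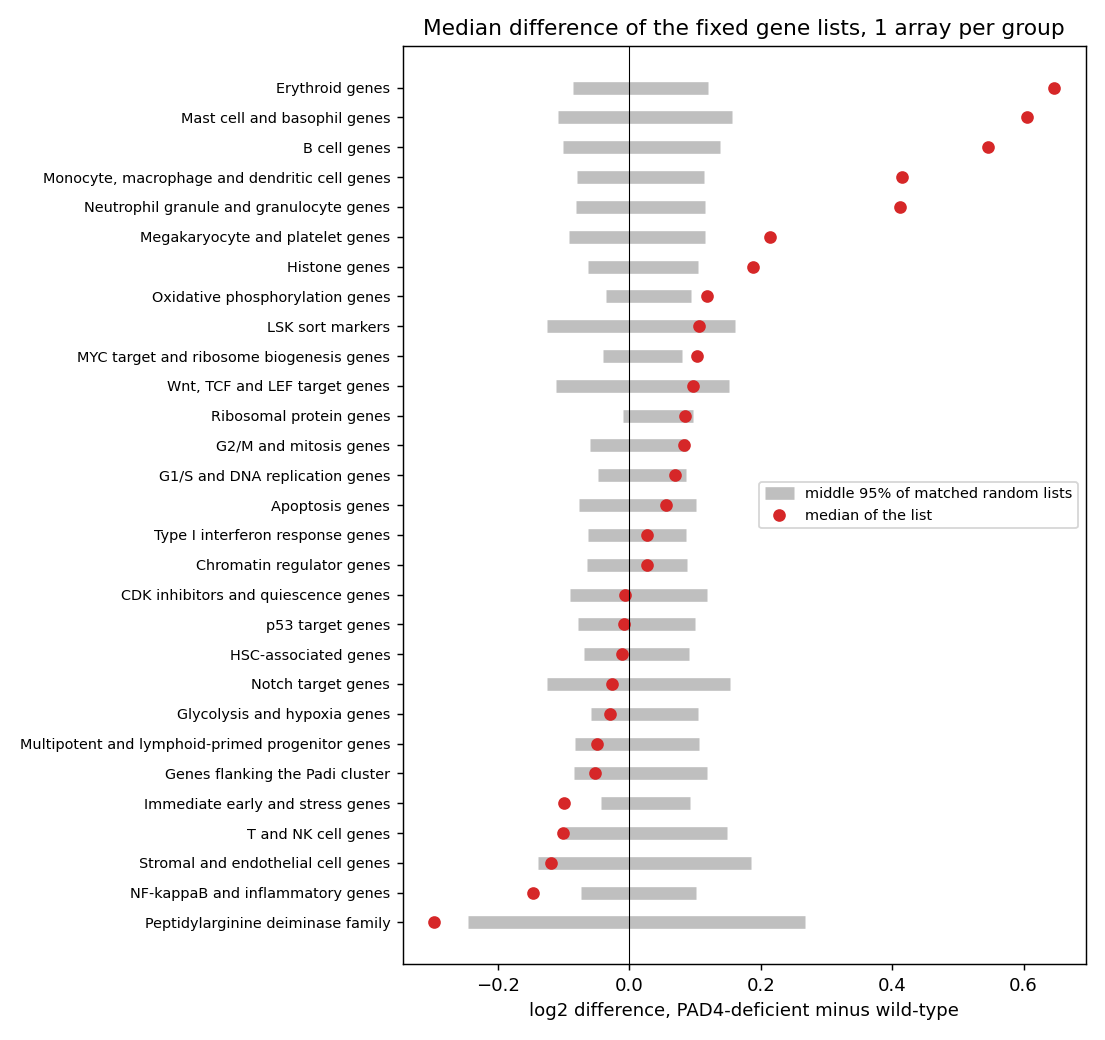
Median log2 difference (x axis, PAD4-deficient minus wild-type, 1 array per group) of 29 gene lists (red points; the sex-linked list is left out), with the middle 95% of random lists matched on mean expression (grey bars). The erythroid median, 0.65, lay furthest above its bar.

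Across all genes, 172 were at least 2-fold higher and 81 at least 2-fold lower on the PAD4-deficient array, 1.49% of those measured, and the median difference was 0.02. The higher genes had a median wild-type signal of 57.0, against 723.9 for all measured genes. The lower genes had a median PAD4-deficient signal of 56.8, against 706.8. Of the higher genes 12.2% and of the lower genes 13.6% had 2 or more measured probes, against 34.5% of all measured genes. Among the 10 largest higher genes, Iglv1, an immunoglobulin lambda variable gene, differed by 4.01 (error 0.22), with 5 measured probes of the same direction. Jchain, which joins secreted antibody chains, differed by 2.46 at 1 probe and 2.36 at the other. Igkv4-55, another immunoglobulin gene, differed by 2.55, and immunoglobulin variable genes are a near-identical family whose probes may bind several members. The others were Tsix (2.94), Gcm2 (2.69), Ermap, Cldn13 (2.35), Cxcl9 (2.29), Plbd1 (2.25) and Olfr1394 (2.23), each from 1 probe. Apart from Plbd1 (656), their wild-type signals lay between 18.0 (Cldn13) and 57.6 (Cxcl9). The lowest signal well above background on that array was 17.7. Besides Padi4, the largest lower genes were Scn2a (-3.57), Nudt12 (-2.75), Myoz3 (-2.71), Dhrs7c (-2.38), Tnp2 (-2.34), Gdf11 (-2.24), P2rx6 (-2.23), Itgb8 (-2.16) and Olfr1497 (-1.98), each from 1 probe with a wild-type signal below 300. With normexp background correction, 67 genes were higher and 24 lower, and 15 of the 20 largest differences were over 1.5 times smaller. Among these, Scn2a had -1.94, Myoz3 -1.12, Tsix 1.46 and Ermap 1.42, while Cldn13 (0.95), Gdf11 (-0.96), P2rx6 (-0.99) and Olfr1497 (-0.82) were no longer 2-fold different. Of the list members named above, Ccr2 (0.95), Pax5 (0.82), Rag1 (0.76) and Cxcl12 (-0.93) were also less than 2-fold different with normexp. Of the 2-fold genes with 2 or more measured probes, all probes passed 1.5-fold in 16 of 21 higher genes and in 2 of 11 lower genes, Padi4 and Ddx3y.

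A further 383 genes were well above background on the PAD4-deficient array only, 117 of them at least 2-fold higher, and 310 on the wild-type array only, 60 of them at least 2-fold lower. Xist, the RNA that silences 1 X chromosome in female cells, was at least 951-fold higher on the PAD4-deficient array, where all 4 of its probes were well above background. Chrna4 (at least 15.6-fold), Vsig4 (15.2-fold), Smad9 (14.9-fold) and Nlrp9b (11.5-fold) came next, each by 1 probe; Chrna4 and Smad9 have a second probe that was not well above background on the PAD4-deficient array. Krt12 was at least 18.3-fold higher on the wild-type array, followed by Tmem117 (8.71-fold), Pglyrp3 (8.09-fold), Sval1 (7.99-fold) and Wdr49 (6.55-fold), each by 1 probe; the second probe of Tmem117 was not well above background on the wild-type array.

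The Y-linked genes Ddx3y, Eif2s3y and Kdm5d were lower on the PAD4-deficient array but well above background there. Ddx3y had a signal of 3455 on the wild-type and 1298 on the PAD4-deficient array, a difference of -1.36, with -1.55 at its second probe. Eif2s3y differed by -1.23 and Kdm5d by -1.17, with errors of 0.20 and 0.21. With normexp Kdm5d differed by -0.79. Uty was well above background on the wild-type array only, at 1 of its probes, and Usp9y on neither array. The 4 sex-linked genes measured on both arrays had a median of -1.20 (percentile 0.0), with Tsix, which overlaps Xist, as the only one higher. The 2 arrays thus differed in sex-linked transcripts as well as in genotype.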

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

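Results were recomputed under alternatives chosen before the data were examined, except the count of genes with 2 or more measured probes, which was chosen after seeing the data. No paired analysis was possible because each group had 1 array, so no replicate could be left out either. The 2-fold counts, 172 higher and 81 lower, became 67 and 24 with normexp background correction, and all of these were among the main genes. They became 506 and 306 with probes well above background on at least 1 array, 1087 and 615 with no filter on signal, 490 and 318 at 1.5-fold, 60 and 24 at 3-fold, and 16 and 2 with 2 or more probes that all passed 1.5-fold. The counts with looser filters take the value of a dim probe as measured. They are thus not comparable with the 117 and 60 genes counted above by at-least folds. The looser filters add dim probes and the other folds change the threshold. The normexp setting adds an offset, which shrinks the differences of dim probes by construction. The main 2-fold genes were dim on 1 side. The higher genes had a median wild-type signal of 57.0 and the lower genes a median PAD4-deficient signal of 56.8. The offset thus lowers both counts. How much of the drop it accounts for was not tested, as the counts were not recomputed without it. The median of the T and NK cell list turned from -0.10 to 0.046 with probes above background on at least 1 array and to 0.19 with no filter, as dim members entered. With normexp the medians were 0.35 for neutrophil, 0.25 for monocyte, 0.24 for B cell and -0.0019 for interferon genes. Median scaling moved all genes by -0.06 alike, which alone accounts for its values: 0.013 for G1/S, 0.027 for G2/M, 0.048 for MYC target, -0.028 for interferon, -0.20 for NF-kappaB, -0.029 for chromatin, 0.13 for histone, 0.028 for ribosomal protein, 0.062 for oxidative phosphorylation and -0.086 for glycolysis genes. The ribosomal protein median was 0.00 with quantile normalization, 0.10 with the percentile of detected probes, 0.024 with loess and 0.068 with the mean over probes. The NF-kappaB median was -0.11 both with the mean over probes and with no filter, and that of the genes flanking the Padi cluster was 0.019 with the mean over probes. The value with the percentile of detected probes is also a shift of all genes alike; the cause of the other shifts was not tested. Padi4 and Myc moved by less than their error under each scaling, the deposited value table and the mean over probes. Signal over background limits the dim genes, whose differences normexp shrinks.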

Other observations

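Of the tests in this part, only the distance test on the array was chosen before its result was seen, and the erythroblast test was also revised after its values were seen; the 3 gene lists added here were also chosen after seeing the data. Among 20 measured genes of type 1 conventional dendritic cells, which present antigen to T cells, 12 were at least 1.5-fold higher and none 1.5-fold lower on the PAD4-deficient array, with a median of 0.69 (percentile 100). Plbd1 differed by 2.25, Batf3, a transcription factor of these cells, by 2.02, and Naaa by 1.65. The 11 members whose values had not been seen when the list was written had a median of 0.49 (percentile 100), with 4 at least 1.5-fold higher. Jaml had 1.36 and Xcr1 0.66 (0.41 with normexp). Wdfy4 (-0.12), Itgax (0.08) and Zbtb46 (0.15) were near 0, and Ifi205 had 0.10 at its brightest probe and 2.55 at another. Clec9a, Tlr3 and Tlr11 were not measured. The list was written after its other members were seen on these arrays, so these 11 are not an independent check. Among 13 plasma cell genes the median was 0.14 (percentile 96.9), and 0.07 (percentile 74.9) over the 10 unseen ones, so the list as a whole did not stand apart, although Irf4 (1.37, and 0.83 with normexp) and Mzb1 (1.11) were higher with Jchain. Of 39 immunoglobulin probes, 12 were at least 2-fold higher and 3, all of the heavy chain locus, at least 2-fold lower. The higher probes were all 5 lambda probes, which belong to 1 gene, 6 of 11 kappa probes and 1 of 23 heavy chain probes. Probes of 1 gene are not independent.

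For the first pattern weighed, the higher level of committed lineage genes, bias from scaling or intensity is argued against for 5 lists. These were the neutrophil, monocyte, erythroid, mast cell and B cell lists. Under normexp, quantile and loess values the lowest of their medians was 0.24, above the middle 95% of matched random lists. The megakaryocyte and platelet list, with a median of 0.17 under normexp, was not compared with random lists under these values. Globin-rich erythroblasts carried over in the sort could not be decided as the cause of the erythroid part. The median of Hba-a1, Hba-a2, Hbb-bt and Alas2 was -0.23. Alas2 (-0.47) and Slc4a1 (0.05), at percentiles 32.0 and 31.2 of the wild-type signals, lay over 2 errors below the erythroid median. These 2 genes were chosen after their values were seen, and other dim erythroid genes went the other way. Eraf, with a wild-type signal of 164, differed by 1.80, and Tspo2, with 315, by 0.89. The globins were bright on the wild-type array (3508 for Hba-a2, 11209 for Hbb-bt). How small a share of erythroblasts would still show in them was not computed. Erythroid progenitors with less of these transcripts stay open too. A sort gate reaching into cells with less Sca-1 also stays open, as Ly6a differed by -0.14, within its error. A true effect of PAD4 deficiency, the sex of the mice and a different share of committed progenitors stay open as well, with 1 array per group.

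The second pattern was lower Y-linked and higher Xist signals. Noise of single probes is argued against, since each of the 4 Xist probes was higher by at least 3.65 on the log2 scale, taken against the lowest wild-type signal well above background. A different sex makeup of the mice is a candidate explanation: the 4 measured probes of Ddx3y, Eif2s3y and Kdm5d kept between 34.2% and 44.4% of the wild-type signal, a range of 0.38 in log2 against 0.42 for 2 errors, but of 0.54 with normexp, whose offset shrinks the differences of dim probes by construction, and of 0.35 with that offset taken off again. Of the 4 measured X-linked genes that escape silencing (median 0.42, percentile 99.9, and 0.25 with the mean over probes), Kdm6a differed by 0.51, Kdm5c by 0.34 and Ddx3x by -0.07, but the 3 probes of Eif2s3x gave 0.57, -0.65 and 0.75, so the escape genes add little. On the wild-type array the 4 Xist probes had signals between 3.67 and 5.38, none well above background, so female RNA was not seen there. Y-linked signal beside Xist may mean RNA of both male and female mice on the PAD4-deficient array. Sex then differs along with genotype in every comparison here.

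The third pattern was the 2-fold genes. Among lower genes with 2 or more measured probes, all probes passed 1.5-fold in 18.2% (exact Clopper-Pearson 95% interval 2.3% to 51.8%), so noise of single probes may account for many of them. Among higher genes the share was 76.2% (52.8% to 91.8%), which argues against such noise in most of the 21 genes with a second probe but not in the 5 that failed, of which Dmrtb1, Pdgfc and Ighg had a probe in the opposite direction, nor in genes with 1 measured probe. A local blemish could not be decided for the lower genes: the median distance to the nearest such probe, at percentile 19.8 of 1000 random probe sets, met the bound set beforehand, but that bound was too weak, since the distance of 10.4 grid units lay below the random median of 11.4.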
